A study of Homo sapiens with 10 samples.

How the data were processed

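Chromatin immunoprecipitation with sequencing was done on human primary liver sinusoidal endothelial cells, the fenestrated endothelium that lines the small blood channels of the liver. Per the labels, cells bought from a commercial supplier were kept without serum for 2 h and then given tumor necrosis factor (TNF) or control treatment for 90 min. Chromatin was cut with micrococcal nuclease and sonication and precipitated with antibodies against histone H3 acetylated at lysine 27 (H3K27ac, a mark of active promoters and enhancers) or against NF-kB. The 10 samples comprised 2 H3K27ac libraries of control cells, 2 of TNF-treated cells, 4 input libraries, and 1 NF-kB library of each treatment. Peak lists of 5 libraries were used: the 4 H3K27ac libraries and the NF-kB library of TNF-treated cells. The input libraries and the NF-kB library of control cells were not analysed here, so NF-kB binding could not be compared between treatments.

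The submitters' processing notes name CASAVA 1.4, Bowtie2, MACS2 and the human genome build hg38. Which step each tool did, the settings, the MACS2 version, any filter and the use of the input libraries were not given in the sources used here. Each of the 5 libraries used had its own deposited list, so their peaks had been called per library and not on pooled samples, per the file headers and names. Each line of a list gives the chromosome, the start and end in bp, a peak name, and the authors' score, whose scale no source names. The authors' score, deposited in the 5th column, was never below 2.00 and was used only to rank or filter peaks within a list. Read numbers were not given in the sources used here, so the depth of each library is unknown. A deeper library can yield more and longer peaks, and no interval below covers that.

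Positions were read as 0-based and are printed 1-based on hg38. Only chromosomes 1 to 22 and X were used. Genes came from a RefSeq table for GRCh38.p14 with 19974 protein-coding genes on these chromosomes. The table gives the span of each gene without its strand, and no genome sequence was used here. The design fixed before the data were examined had set windows and distances from transcription start sites. They were taken from gene spans instead: a window is the span plus 50 kb on either side, the nearest gene is the nearest span, and the promoter exclusion is 2.5 kb around both ends of a span. A planned search for the kB motif was not run for want of a genome sequence.

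Peaks of the 4 H3K27ac lists were merged where they overlapped. A merged region counted as occupied in a library when at least 1 bp of its peaks lay in it. Regions in both TNF libraries and neither control library were called gained, those in both control libraries and neither TNF library lost, and those in all 4 libraries shared. No p-value was attached to these classes, because an exact two-sided permutation test of 2 libraries against 2 cannot go below 0.333. The same counts were made for the crossed pairs of 1 control and 1 TNF library.

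For each gene, the length covered by H3K27ac peaks in its window was computed per library. Genes with a mean of at least 1000 bp over the 4 libraries were tested. Values were log2 of the covered length plus 500 bp, and each library was centred on its median. Log2 changes are on this scale, which understates the change of genes with little cover. Groups were compared with limma-trend (limma 3.58.1, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors (SE) are limma's moderated ones. Genes whose windows overlap share peaks and are not independent, and the 15170 genes tested formed 2619 groups of overlapping windows. On simulated values with the means and moderated spread of these genes, 200 of the 15170 were changed. The test recovered 72% of changes of 0.5 and 97% of changes of 1 on the log2 scale, with 10 calls among unchanged genes. The simulated genes were normal and independent, unlike the real ones, so these figures do not measure the errors in these data.

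A total of 17 gene lists were fixed before the data were examined: CXC chemokines, CC chemokines, leukocyte adhesion, NF-kB pathway and feedback, cytokines and inflammatory signalling, immediate early and stress, interferon response, coagulation and fibrinolysis, pan-endothelial identity, liver sinusoidal endothelial identity, shear and quiescence, lymphatic endothelial, hepatocyte, hepatic stellate and fibroblast, macrophage and leukocyte, cholangiocyte and epithelial, and housekeeping. They were tested with camera at a preset correlation of 0.01 and adjusted over the 17 lists. The test with an estimated correlation was the alternative. The covered length of the cell type lists was also set against 10000 random lists of the same size matched on window length, a description added after the covered lengths were seen.

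NF-kB peaks were compared with the region classes by overlap of at least 1 bp, with 95% Wilson intervals and 1000 random placements on the same chromosome. The number of genes of each list with an NF-kB peak in the window was ranked among 10000 random lists matched on covered length. With 1 library there is no p-value, and intervals cover counting error only. For stitched domains, peaks at least 2.5 kb from the ends of gene spans were joined within 12.5 kb. Domains were ranked by covered length within each library, and those past the point where the scaled rank curve has a slope of 1 were counted. The usual ranking of super enhancers uses read signal, for which covered length stands in.

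The genes and regions named were chosen by a rule fixed before the data were examined: the 12 gained and 12 lost regions of highest mean score percentile, the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold and moved alike in all control-TNF pairs, the 15 NF-kB peaks of highest score, 12 inflammatory genes in every case, and the members of each list with the largest changes. Values of some single genes, and the number of coagulation and fibrinolysis genes near NF-kB peaks, are not reported here. The alternatives were other score thresholds, equal list lengths, other overlaps and merging gaps, other windows, pseudocounts and filters, no centring, a replicate block, other stitching, and leaving out each library in turn. Intervals were handled in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The interval functions were tested on simulated lists of 20000 intervals against bedtools 2.31.1, with 0 differences, and found 500 of 500 planted gained and 500 of 500 planted lost regions. Figures were drawn with matplotlib 3.10.9.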

Results

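H3K27ac peaks were mapped in liver sinusoidal endothelial cells after 90 min of TNF, an inflammatory cytokine that acts on endothelium through the transcription factor NF-kB, or of control treatment, with 2 libraries per group. NF-kB peaks came from 1 library of TNF-treated cells. The H3K27ac lists held 109377 and 105977 peaks in the control libraries and 106145 and 105250 in the TNF libraries, which covered 81.3, 67.3, 77.0 and 75.7 Mb. The NF-kB list held 1153 peaks with a median width of 179 bp. Control 1 and control 2 shared 65.5% of the bp covered by either, TNF 1 and TNF 2 shared 68.0%, and pairs across the groups shared 58.5% to 60.3%. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical. Read depth is unknown.

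The first comparison asked where H3K27ac appeared or disappeared with TNF. Of 130569 merged regions, 50137 were shared by all 4 libraries, 7314 were gained and 7340 were lost. Gained regions covered 4.03 Mb with a median width of 460 bp, and lost regions 3.25 Mb with a median of 396 bp. The classes differed in the upper part of the authors' scores: 342 gained regions had a mean score percentile of at least 75 within their lists, against 12 lost regions. The highest-ranking gained regions lay 50.4 and 51.9 kb from LOC124903391 (chr14:103259247-103260622 and chr14:103260798-103262195), inside TEN1 (chr17:75996929-75997346), 50.4 kb from EIF3M (chr11:32531853-32533405) and inside ZFAND3 (chr6:38131992-38135637). Next came regions inside EHMT1, NSL1, DOCK10, USP40, NPAS3, BTN2A2 and TRIQK. The highest-ranking lost regions lay inside CHN2 (chr7:29499324-29500860) and at 3 places 145.9 to 215.2 kb from ZNF32 on chromosome 10 (chr10:43864075-43865007, chr10:43794820-43795620 and chr10:43857887-43859286). Other lost regions lay inside HSF2BP, MXRA7, TCEA3 and OSBPL9, 0.222 kb from CCDC88A, 35.9 kb from LDLRAD3, 41.4 kb from DNAJC11 and 1341 kb from SUCLG1.

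Crossed pairs of 1 control and 1 TNF library held fewer regions of their own: 2669, 1161, 2543 and 1257. In these pairs, 0, 0, 0 and 1 regions reached a mean score percentile of 75. The class counts depend on the list threshold and on each library. With only peaks above the median score of each list, 4026 regions were gained and 3777 lost, and leaving out any 1 library gave 9287 to 20992 gained and 11034 to 24239 lost.

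**Figure D1:**
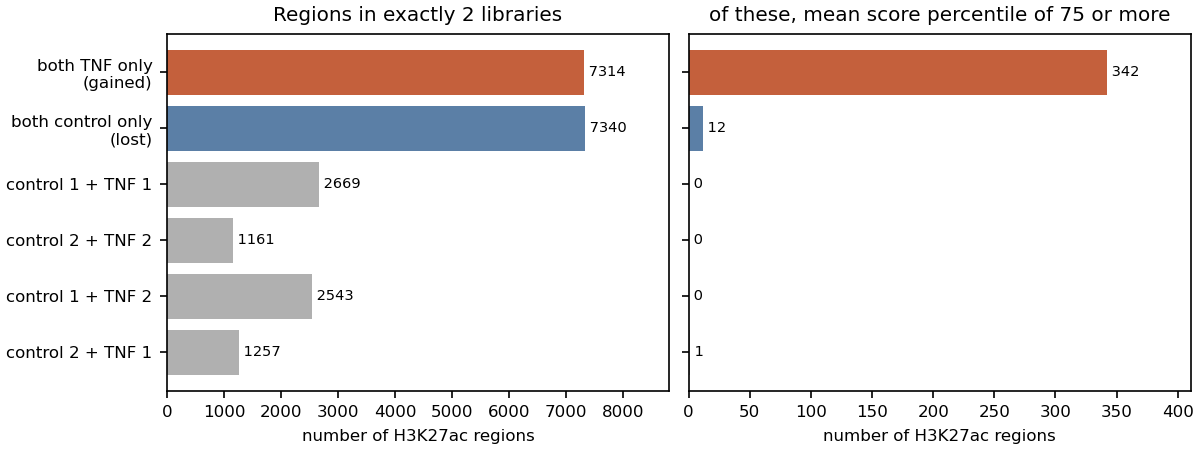
Number of H3K27ac regions present in exactly 2 of the 4 libraries, by the pair that held them, for all regions (left) and for those with a mean score percentile of at least 75 (right). Both TNF libraries held 7314 regions and both controls 7340, against at most 2669 for a crossed pair, and at the right 342 against 12.

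The covered length around genes moved both ways with TNF. Of 15170 genes tested, 2690 had more H3K27ac-covered length in TNF-treated cells and 2725 had less, and changes of at least 1 on the log2 scale were found for 331 higher and 141 lower genes. IL1A, which encodes the cytokine interleukin 1 alpha, rose from 4.93 ± 1.47 to 32.7 ± 2.51 kb (SD, n = 2 per group; log2 change 2.65, SE 0.10, limma adjusted p = 3.81e-16), with a log2 change of 1.36 in windows of 10 kb and 1.70 in windows of 100 kb. Other large rises were at genes with hardly any cover in control cells. VPS41 went from 0.171 to 5.67 kb, RBFOX3 from 0.099 to 3.78 kb and WNK2 from 0.242 to 4.45 kb. KRTAP5-7, KRTAP5-8, BTBD8, NKD2, SLC12A7 and B3GAT2 were listed at 0 in both controls and had means of 3.77, 3.63, 2.73, 2.31, 2.31 and 2.20 kb with TNF. NKD2 and SLC12A7 are neighbours with the same peaks, and so in large part are KRTAP5-7 and KRTAP5-8.

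The largest falls included 3 neighbours on chromosome 8. PNOC, the precursor of the neuropeptide nociceptin, fell from 8.61 ± 2.14 to 1.03 ± 0.14 kb (log2 change -2.55, SE 0.16, limma adjusted p = 2.77e-12), ZNF395 from 15.6 to 2.83 kb and FBXO16 from 11.6 to 2.29 kb. NR1H4, which encodes the bile acid receptor FXR, fell from 2.77 to 0.102 kb, and IGFBP5, a binding protein of insulin-like growth factors, from 3.20 to 0.403 kb. CROCC2 fell from 2.71 to 0.157 kb, SCN10A from 5.27 to 0.74 kb and PADI3 from 5.81 to 0.933 kb. LSP1 and TNNI2, which share their peaks, fell from 2.63 to 0.294 kb. Without centring, 1460 genes were higher and 1347 lower, and windows of 10 kb gave 1677 and 1535.

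Several chemokine genes gained cover. Of 10 measured CXC chemokines, 6 rose, none fell and 4 did not pass; adjusted over the list alone, 9 rose and none fell. All 6 lie in the cluster on chromosome 4 from CXCL8 to CXCL2 (chr4:73740569-74099195) and in part share peaks. CXCL8, the main neutrophil attractant in humans, rose from 18.6 ± 3.08 to 40.2 ± 0.28 kb (log2 change 1.11, SE 0.07, limma adjusted p = 1.98e-12), with a log2 change of 2.19 in windows of 10 kb. CXCL1 rose from 9.10 to 22 kb, CXCL3 from 5.37 to 12.6 kb, CXCL6 from 8.63 to 18.7 kb, CXCL2 from 10.02 to 19.1 kb and CXCL5 from 6.87 to 12.9 kb. CXCL9, CXCL10 and CXCL11 share a window that went from 2.70 to 3.61 kb and did not pass (adjusted p = 0.055). The list was higher by camera (adjusted p = 3.56e-07, and adjusted p = 0.169 with an estimated correlation). The 10 genes stood for 4 separate groups of windows. With 1 gene per window, a setting chosen after seeing the data, camera gave an adjusted p of 0.0209.

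Of 9 measured CC chemokines, 5 rose and none fell, over all genes and adjusted over the list alone. CCL5 rose from 2.01 to 11.2 kb, CCL2, the main monocyte attractant, from 5.6 ± 0.51 to 24.0 ± 0.60 kb (log2 change 2.02), and CCL8 from 0.554 to 2.56 kb. CCL7, CCL8 and CCL11 lie near CCL2 with windows that overlap, so the 9 genes stood for 6 separate groups of windows. The list median was 1.55, and 0.13 with 1 gene per window, a setting chosen after seeing the data (camera adjusted p = 0.0436). CCL20 (13.3 and 14.5 kb), CCL24, CCL28 and CCL21 did not pass. The list was higher by camera (adjusted p = 8.26e-06; adjusted p = 0.398 with an estimated correlation).

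Of 7 measured leukocyte adhesion genes, 4 rose and 1 fell, over all genes and adjusted over the list alone. ICAM1 rose from 9.31 ± 1.82 to 16.4 ± 0.79 kb and VCAM1 from 9.31 ± 0.68 to 15 ± 0.93 kb; both are ligands for leukocyte integrins. CD47, which signals against engulfment, rose from 2.34 to 6.45 kb, and MADCAM1 fell from 6.43 to 4.77 kb. SELE, the endothelial selectin, had too little cover to be tested, with 699 and 468 bp in the controls and 731 and 0 bp with TNF. The list was higher by camera (adjusted p = 0.0448; adjusted p = 0.386 with an estimated correlation), and its call was lost without control 1 (adjusted p = 0.074) and with windows of 10 kb.

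Genes of the NF-kB pathway and its feedback also gained cover. Of 20 genes, 15 rose and none fell; adjusted over the list alone, 16 rose. TNFAIP3, which encodes the feedback inhibitor A20, rose from 16.9 ± 1.56 to 50.01 ± 2.63 kb (log2 change 1.56, SE 0.07, limma adjusted p = 4.64e-15). CYLD rose from 0.963 to 3.71 kb, BIRC2 from 5.79 to 16.7 kb and TNIP1 from 11.1 to 30.3 kb, and NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, rose from 10.9 ± 0.94 to 22 ± 0.60 kb. Genes of the NF-kB subunits parted: NFKB1 (8.28 to 20.4 kb) and NFKB2 (5.72 to 10.3 kb) rose, while RELA (14.4 and 15 kb), RELB (5.06 and 5.04 kb) and REL (3.45 and 3.32 kb) did not pass. The list was higher by camera (adjusted p = 8.10e-13; adjusted p = 0.169 with an estimated correlation).

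Of 16 measured genes for cytokines and inflammatory signalling, 13 rose and none fell, over all genes and adjusted over the list alone. Beside IL1A, CSF2 rose from 3.97 to 17.7 kb and IL1B from 9.77 to 39.1 kb. TNFSF10, which encodes the death ligand TRAIL, rose from 2.62 to 6.48 kb. The windows of IL1A and IL1B overlap, so their rises are not independent, and the 16 genes stood for 14 separate groups of windows. The list was higher by camera (adjusted p = 2.42e-11; adjusted p = 0.169 with an estimated correlation). Interferon response genes rose in 11 of 15 cases and none fell; adjusted over the list alone, 13 rose and 1 fell. GBP2 rose from 3.04 to 6.96 kb, the transcription factor gene IRF1 from 16.3 to 31.5 kb and GBP1 from 4.71 to 9.01 kb, and the list was higher by camera (adjusted p = 6.33e-06; adjusted p = 0.386 with an estimated correlation). IRF7 (6.46 and 4.95 kb) did not pass over all genes. The 15 interferon response genes stood for 11 separate groups of windows, and the windows of GBP1 and GBP2 overlap. With 1 gene per window, camera gave this list an adjusted p of 9.0e-04.

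**Figure D2:**
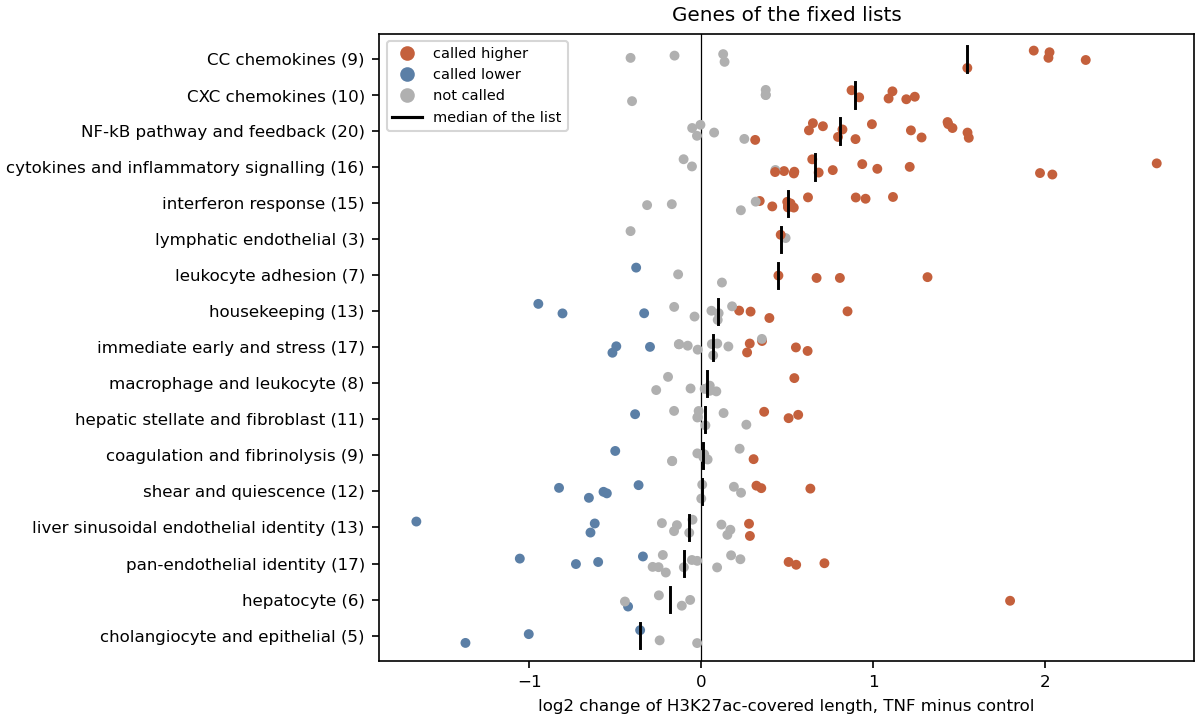
Log2 change of H3K27ac-covered length with TNF (x axis) for each measured gene of the 17 fixed lists (number measured in brackets), with points coloured by the limma call and a black bar at the list median. Medians ran from -0.35 for cholangiocyte and epithelial genes to 1.55 for CC chemokines, whose median was 0.13 with 1 gene per window.

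Lists of endothelial function were not called as lists, with members on both sides. Of 17 measured pan-endothelial genes, 3 rose and 4 fell; adjusted over the list alone, 3 rose and 5 fell (camera adjusted p = 0.83). The angiopoietin receptor gene TEK rose from 25 to 41.0 kb, FLI1 from 23.8 to 34.7 kb and CDH5, which encodes VE-cadherin, from 4.68 to 6.79 kb. EGFL7 fell from 3.12 to 1.23 kb, ESAM from 15 to 8.76 kb, FLT1 from 1.98 to 1.11 kb and the nitric oxide synthase gene NOS3 from 7.34 to 5.63 kb. Of 13 measured genes of liver sinusoidal endothelial identity, 2 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.624). FCN2 fell from 2.29 to 0.383 kb, the mannose receptor gene MRC1 from 4.95 to 2.90 kb and the scavenger receptor gene STAB2 from 2.72 to 1.54 kb.

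Of 12 measured genes of shear response and quiescence, 3 rose and 5 fell; adjusted over the list alone, 4 rose and 5 fell (camera adjusted p = 0.83). ID1 fell from 11.6 to 6.25 kb, HES1 from 1.84 to 0.977 kb, SMAD6 from 11.8 to 7.68 kb and KLF2, a flow-induced transcription factor gene, from 9.21 ± 1.35 to 6.04 ± 0.05 kb, while HEY2 rose from 9.18 to 14.2 kb. The list median was 0.004, its mean -0.10 and the test pointed down; with windows of 10 kb the median was -0.45 (camera adjusted p = 0.056). For coagulation and fibrinolysis, 1 of 9 measured genes rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.929). VWF, von Willebrand factor, fell from 9.47 to 6.45 kb and TFPI rose from 32.3 to 39.7 kb. The list median was 0.01, its mean -0.03 and the test pointed down. Among 17 immediate early and stress genes, 5 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.624). EGR1 rose from 2.58 to 4.12 kb and ATF3 from 3.27 to 4.96 kb, while JUN fell from 30.1 to 20.6 kb and FOS from 5.20 to 3.51 kb.

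Markers of other cell types were examined the same way. Several genes of hepatic stellate cells and fibroblasts were heavily covered in all 4 libraries: COL1A1 50.1 ± 1.61 kb, COL1A2 49.7 ± 1.61 kb, COL3A1 54.2 ± 3.52 kb and the platelet-derived growth factor receptor gene PDGFRB 26.5 ± 2.91 kb (SD over the 4 libraries). The PDGFRB window overlaps that of the macrophage gene CSF1R. Other stellate and fibroblast genes had little, with 3.95 ± 0.48 kb at TWIST1 and 3.91 ± 0.87 kb at DES. LRAT, which marks quiescent stellate cells, was listed at 0 in each library. The list median was 20.7 and 17.0 kb in the controls and 23.8 and 23 kb with TNF, above 100% of random lists matched on window length in each library. Pan-endothelial genes had medians of 6.59, 4.29, 5.6 and 5.52 kb, above 85.3%, 62.1%, 79.7% and 80.1% of random lists; PECAM1 had 9.33 ± 1.6 kb, CDH5 5.73 ± 1.34 kb and KDR 5.49 ± 0.95 kb, while TEK had 33.0 ± 9.30 kb, FLI1 29.3 ± 6.51 kb and ENG 25.4 ± 3.14 kb. Genes of liver sinusoidal endothelial identity had medians of 5.92, 3.97, 2.72 and 3.08 kb, above 73.3%, 52.2%, 16.9% and 25.9% of random lists, with GATA4 far above the rest at 60.9 ± 3.60 kb. Some endothelial genes had hardly any cover, with means of 0.046 kb at TAL1, 0.89 kb at LMO2, 0.14 kb at CLEC1B and 0.28 kb at OIT3. Hepatocyte genes had medians of 0.992, 0.843, 0.994 and 0.814 kb, and macrophage and leukocyte genes 3.77, 3.54, 4.05 and 3.44 kb. Housekeeping genes had medians of 10.77, 8.78, 13.34 and 12.76 kb, above 99.49%, 99.37%, 99.97% and 99.95% of random lists.

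**Figure D3:**
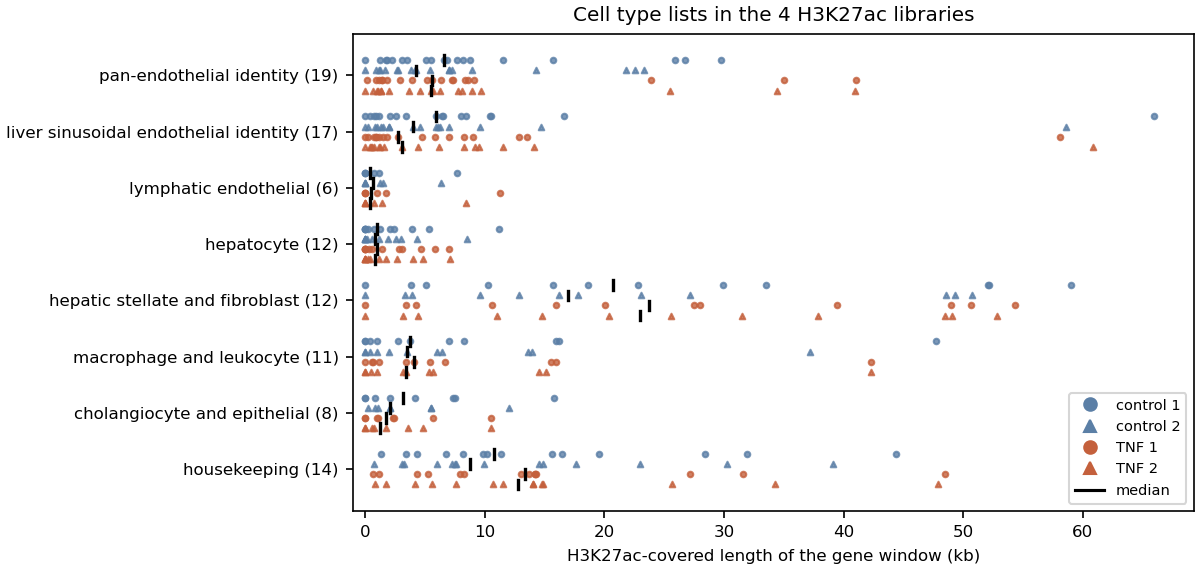
H3K27ac-covered length of the gene window in kb (x axis) for each gene of the 8 cell type and housekeeping lists (number of genes in brackets), with 1 row of points per library and a black bar at its median. The stellate and fibroblast medians of 17.0 to 23.8 kb lie above those of every other list drawn.

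With TNF, 3 of 11 measured stellate and fibroblast genes rose and 1 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.325). ACTA2, smooth muscle actin, rose from 20.3 to 29.8 kb, LUM from 14.3 to 20.2 kb and DCN from 30.3 to 38.7 kb, and DES fell from 4.53 to 3.29 kb. Of 5 measured cholangiocyte and epithelial genes, none rose and 3 fell, over all genes and adjusted over the list alone. CFTR, a chloride channel gene, fell from 3.10 to 0.837 kb, the splicing regulator gene ESRP1 from 6.54 to 2.99 kb and the keratin gene KRT7 from 13.9 to 10.6 kb. That list was lower by camera (adjusted p = 0.0259; adjusted p = 0.386 with an estimated correlation), and its call was lost without control 1 (adjusted p = 0.074) and with windows of 10 and 100 kb. For hepatocyte genes 1 of 6 measured rose (SERPINA1, 1.18 to 5.32 kb) and 1 fell (APOA1, 9.86 to 7.08 kb), over all genes and adjusted over the list alone (camera adjusted p = 0.847), with a median of -0.18, a mean of 0.08 and a test that pointed down. LYZ rose from 2.35 to 3.60 kb as the 1 called gene among 8 measured of macrophages and leukocytes, over all genes and adjusted over the list alone (camera adjusted p = 0.929). RELN rose from 7.03 to 9.83 kb as the 1 called gene of 3 measured lymphatic genes, over all genes and adjusted over the list alone (camera adjusted p = 0.624). Of 13 measured housekeeping genes, 4 rose and 3 fell, over all genes and adjusted over the list alone (camera adjusted p = 0.83). YWHAZ rose from 7.68 to 14.1 kb and PGK1 fell from 3.25 to 1.45 kb, and the list had a median of 0.10, a mean of -0.01 and a test that pointed up.

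The next comparison set NF-kB peaks of TNF-treated cells beside H3K27ac. Of 1153 NF-kB peaks, 841 (72.9%, 95% Wilson interval 70.3% to 75.4%) lay in regions of both TNF libraries and 685 (59.4%, 56.5% to 62.2%) in regions of both control libraries; random placements gave means of 3.59% and 3.61%. NF-kB peaks lay in 129 of 7314 gained regions (1.76%, 1.49% to 2.09%) and 715 of 50137 shared regions (1.43%, 1.33% to 1.53%). They lay in 0 of 7340 lost regions, which allows a share of up to 0.0409%. Within 1000 bp the share was 0.0272%. Random placements gave mean shares of 0.0309% for gained, 0.0757% for shared and 0.0261% for lost regions. The 0 in lost regions thus lies below the gained and shared shares but cannot be told from random placement. Within 2 kb of NF-kB peaks, both TNF libraries had more H3K27ac-covered length than both controls at 801 peaks (69.5%) and less at 37 (3.21%). At shared regions without an NF-kB peak the shares were 24.1% and 27.5%, and chance gives 16.7% each way. These sets are unlike. The NF-kB peaks include 123 in gained regions, which only the TNF libraries hold, while shared regions are held by all libraries. A part of the gap may follow from these definitions. By position, 26.9% of NF-kB peaks lay within 2.5 kb of an end of a gene span, 38.2% farther inside a span and 34.95% outside.

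The NF-kB peak with the highest score overlapped the lower end of the CXCL8 span (chr4:73740374-73740707), where H3K27ac within 2 kb covered 1196 and 725 bp in the controls and 3725 and 3765 bp with TNF. The next lay in CD82 (chr11:44569239-44569441), a gained region, and 0.064 kb from SMPD1 (chr11:6390101-6390409), a shared region. Around the CD82 peak, H3K27ac within 2 kb covered 1070 and 754 bp in the controls and 3698 and 3774 bp with TNF. A peak 20 kb from LRRC32 (chr11:76690748-76691088) lay in a gained region with 2812 and 2478 bp of H3K27ac with TNF and 0 bp in both controls, and a peak in IL4I1 (chr19:49897730-49897991) lay in a gained region with 1664 and 1868 bp against 0 bp. Peaks also lay in NFKB2 (chr10:102394389-102394731) and 61.7 kb from NFKB1 (chr4:102439359-102439695), both in shared regions. The others of the 15 were in or near ARSG, TMEM184B, ATG16L2, FEM1C, CCDC57, ARL14EP, MAP2K3 and SAMD9, all in shared regions.

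Genes whose cover rose had NF-kB peaks nearby more often. An NF-kB peak lay in the window of 842 of 2690 higher genes (31.3%, 29.6% to 33.1%), 151 of 2725 lower genes (5.54%, 4.74% to 6.46%) and 926 of 9755 genes not called (9.49%). Genes of equal covered length had 16.0%, 12.8% and 11.7%. Neighbouring genes can share an NF-kB peak, so these intervals, which take genes as independent, are too narrow. Among the lists, 18 of 20 NF-kB pathway genes had an NF-kB peak (mean of random lists 3.20, above 100% of them), as had 7 of 12 CXC chemokines (1.36, 99.99%), 6 of 12 CC chemokines (1.05, 100%) and 8 of 17 cytokine genes (2.84, 99.8%). With windows of 10 kb the CC chemokines with a peak numbered 1 and the cytokine genes 5, and with NF-kB peaks above their median score 3 CC chemokines had a peak. CCL2, CCL7, CCL8, CCL11 and CCL13 have windows that overlap in a chain, and CXCL9, CXCL10 and CXCL11 share a window. CXCL1 and CXCL6 hold the same NF-kB peak. The windows of IL1A and IL1B, of TNF and LTB, and of BIRC2 and BIRC3 overlap as well. The same NF-kB peaks therefore count several times in these numbers and percentiles. Immediate early genes had 6 of 17 and interferon response genes 5 of 16, above 89.4% and 89.9% of random lists, and 3 and 2 with either of these settings. Of the rest, housekeeping had 3, liver sinusoidal identity 2, macrophage and leukocyte 2, and leukocyte adhesion (ICAM1), pan-endothelial (TEK), shear (HEY2) and hepatocyte (SERPINA1) 1 each. Lymphatic, stellate and fibroblast, and cholangiocyte genes had 0; random lists like the stellate and fibroblast list had a mean of 2.57.

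**Figure D4:**
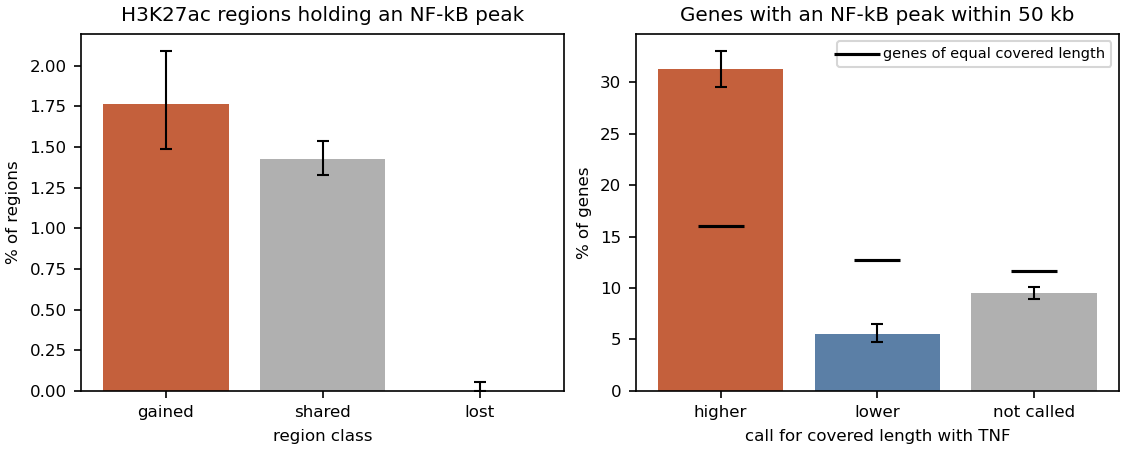
Share of H3K27ac regions that hold an NF-kB peak, by region class (left), and share of genes with an NF-kB peak in the window, by call (right); bars are percents, error bars 95% Wilson intervals and black lines the share in genes of equal covered length. Gained regions reach 1.76% and lost regions 0%, and higher genes 31.3% against 5.54% of lower genes. The error bars take neighbouring genes and regions as independent.

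Because the series is about super enhancers, stitched H3K27ac domains were described last. The largest domain at the CXC chemokine cluster lay beside CXCL8 in each library, ending before the gene span in both controls and TNF 1 and running past it in TNF 2. These ends follow from the exclusion of 2.5 kb around the ends of gene spans, since peaks lay in the CXCL8 span in all 4 libraries. TNF 2 ran past through a peak beyond that zone (chr4:73746635-73746933). The domain held 24135 bp of peaks in control 1 (chr4:73660466-73735804) and 19198 bp in control 2 (chr4:73660836-73735191). With TNF it held 45655 bp in TNF 1 (chr4:73660109-73737813) and 46577 bp in TNF 2 (chr4:73659026-73746933). By covered length it ranked 237 and 246 within the control lists and 69 and 71 within the TNF lists, and it was above the slope threshold in all 4. From CXCL8 to CXCL2, 43 and 37 peaks covered 22135 and 17601 bp in the controls, and 72 and 66 peaks covered 49515 and 46727 bp with TNF; 3 NF-kB peaks lay there. Genome-wide, 1130 and 1053 domains of the control libraries and 1045 and 948 of the TNF libraries passed the threshold. The stretch in which the domains were described was extended by 50 kb on either side after the data were seen, and no test was run on domains.

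**Figure D5:**
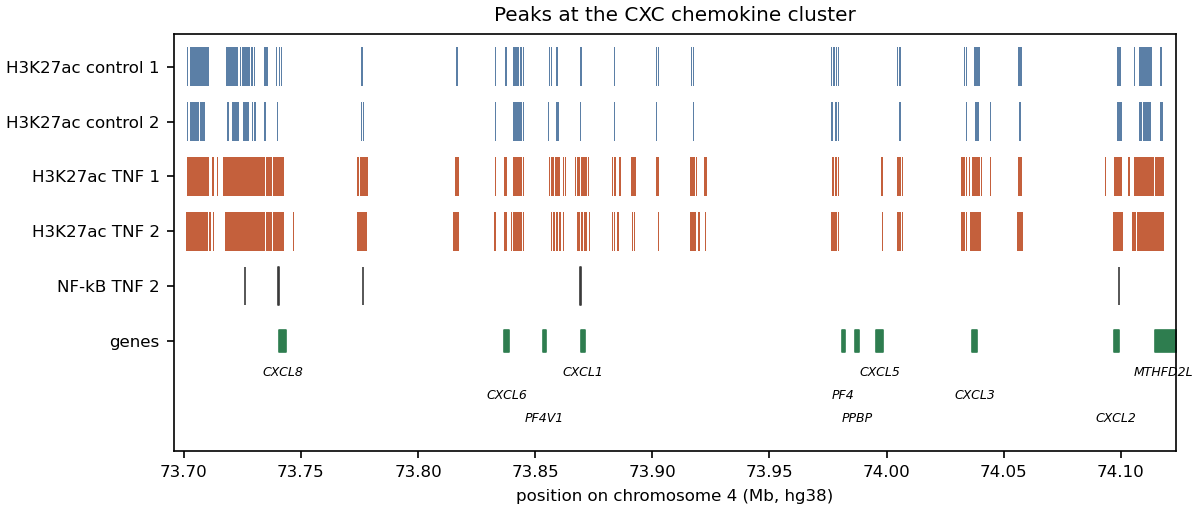
Map of peaks at the CXC chemokine cluster on chromosome 4 (x axis in Mb, hg38), with H3K27ac peaks of the 4 libraries, NF-kB peaks of TNF-treated cells and protein-coding genes. From CXCL8 to CXCL2 the peaks cover 22135 and 17601 bp in the controls and 49515 and 46727 bp with TNF.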

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

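The use of the highest-scoring 25% of each list, of member peaks above the median score against whole lists of the other group, of 1 gene per window and of the extended CXC stretch were chosen after seeing the data. Gained and lost regions numbered 7314 and 7340. They numbered 4026 and 3777 with peaks above the median score of each list, 2264 and 2796 when merged within 1000 bp, 2593 and 2142 with the highest-scoring 25%, and 1407 and 613 when both member peaks had to lie above the median score and the other group's lists were kept whole. Without 1 library, gained regions ranged from 9287 to 20992 and lost from 11034 to 24239, since fewer libraries had to match; the stricter settings leave fewer peaks or join them. Genes higher and lower numbered 1677 and 1535 with windows of 10 kb and 1460 and 1347 without centring, and 52.0% of calls were then higher, against 49.7%; the cause was not tested. Without 1 library they ranged from 2231 to 2292 and from 1870 to 2207, with the lone sample of a group assumed to vary like the other group. For the genes with the largest rises and falls and the fixed inflammatory genes, each value kept its direction and its side of the threshold wherever the gene was still tested; single list members were not run under the alternatives. Sizes moved more: with windows of 10 kb CXCL1 had a log2 change of 2.34 against 1.24, ICAM1 1.98 against 0.81, CCL2 1.30 against 2.02 and CXCL6 0.34 against 1.09, and with windows of 100 kb WNK2 had 0.46 against 2.79. Genes near 0 in a group followed the pseudocount, as KRTAP5-7 with 5.28 at 100 bp and 1.54 at 2000 bp against 3.10. With an estimated correlation 0 of the 17 lists were called instead of 7. That test estimates the correlation, and takes its p-value, from 2 residual degrees of freedom. The estimates were -0.034 for CXC chemokines, -0.114 for leukocyte adhesion, 0.019 for NF-kB pathway and 0.029 for cytokine genes. Epithelial, interferon response and CC chemokine genes had 0.051, 0.138 and 0.522. For CXC chemokines and adhesion the estimate lay below the preset 0.01, so correlation does not explain their lost calls. The other list alternatives called 5 to 7. The share of NF-kB peaks in regions of both TNF libraries was 85.6% within 1000 bp and 68.6% with H3K27ac peaks above the median score. The shares of gained and shared regions with an NF-kB peak were 1.16% and 0.778% with NF-kB peaks above their median score, 5.43% and 2.16% within 1000 bp, and 4.47% and 1.90% with H3K27ac peaks above the median score. The share of lost regions was 0.0272% within 1000 bp and 0% in the other settings. Stitched domains and the number of lists near NF-kB peaks stayed within 1.5 times of the reported counts, but 17 of 51 counts of list genes near NF-kB peaks did not. The motif alternatives were not run. Depth is unknown, so its part in list length and peak width could not be measured.

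With a replicate block, 2821 genes were higher and 2920 lower, and 7 lists were called. The samples share only a number: the correlation of same-numbered deviations was 0.0095, from 2 pairs. The crossed groupings of the 4 libraries, which put 1 control and 1 TNF library on each side, called 0 genes by limma, with 17 and 32 genes at an unadjusted p under 0.05. In those fits the treatment difference adds to the residual spread, so their low counts say little.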

Other observations

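The counts by stretch of 1 Mb, the tests of gene spans and of TNF treatment for the fibroblast genes, and the resampled intervals of their scores were chosen after the results were seen. A pattern weighed earlier, the similar numbers of gained and lost regions, was set aside in favour of the fibroblast genes after its tests had been seen; its values were 2669 regions for the largest crossed pair and 7496 gained with lists of equal length.

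The stretch with the most gained regions was chr6:137000001-138000000, around TNFAIP3, with 42 gained and 2 lost regions. It was followed by chr7:41000001-42000000 with 25, around INHBA, an activin subunit gene, and by chr3:188000001-189000000 at LPP with 24. The fullest stretches of lost regions held fewer, with 18 in chr2:18000001-19000000 and 17 in chr6:121000001-122000000, where the gap junction gene GJA1 lies. In the gained regions of the named stretches, NF-kB peaks numbered 3 around INHBA, 0 around TNFAIP3 and 0 at LPP. Outside all H3K27ac regions lay 292 NF-kB peaks (25.3%). Their median score percentile in the NF-kB list was 48.0, against 50.3 for the 672 peaks in shared regions, 63.3 for the 123 in gained regions and 41.2 for the 66 in other regions.

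In lost regions, random placements gave a mean share of only 0.0261%, so a count of 0 there cannot be told from random placement. NF-kB peaks lay in gained regions and in none of the lost ones. Differences in length and score did not account for all of this: among 6058 gained regions matched to 6058 lost regions on both, 1.04% (0.814% to 1.33%) held an NF-kB peak, against 0 of the lost (Wilson upper bound 0.0634%). They may account for a part, since 1.76% of all gained regions held one. At like length and score, NF-kB peaks did not mark regions of TNF-treated cells alike. Of 5108 shared regions matched to gained ones on both, 0.352% (0.223% to 0.556%) held a peak, against 2.41% (2.02% to 2.87%) of those gained regions. These shared regions are low-scoring for their class, with a median score percentile of 42.5 against 71.5 for all shared regions. Over whole classes the shares were closer, with 1.43% of shared and 1.76% of gained regions. A candidate explanation is that NF-kB binding goes with gained acetylation and that loss takes place without NF-kB on the same sequence. A gained region can lie beside acetylation present in the controls, as at CD82. Merging within 1000 bp left 2264 gained and 2796 lost regions. This candidate explanation was drawn from the same data as the tests above, which addressed other explanations, and it was not itself tested. NF-kB binding before TNF was not analysed here.

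Most gained regions held no NF-kB peak. The hypothesis that they cluster around NF-kB peaks was tested on 7185 of them: 21.5% lay within 50 kb of an NF-kB peak, against 5.42% of lost and 9.92% of shared regions without one. Denser acetylation did not account for all of this by count of regions. Of gained regions matched to lost ones on H3K27ac density, 19.97% lay that near, against 5.81% of the lost. Neighbouring regions were counted singly and are not independent. The stretch around TNFAIP3 alone held 42 gained regions, so 1 NF-kB peak can lie near many. How many separate loci carry the difference was not counted. A part of the gained regions may thus form in the neighbourhood of bound NF-kB, while the larger part lay more than 50 kb from any peak in this list. A weak NF-kB peak below the caller's threshold was not tested.

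The median gene of the stellate and fibroblast list had more acetylated sequence than the median pan-endothelial gene in each library. Single pan-endothelial genes ranged widely. TEK, FLI1 and ENG were covered like PDGFRB, while SOX17 had 1.52 kb, SOX18 1.45 kb, LMO2 0.89 kb and TAL1 0.046 kb. LRAT of the stellate and fibroblast list was listed at 0. No gene of that list stands in another list, but the PDGFRB window overlaps that of CSF1R of the macrophage and leukocyte list. How many stellate and fibroblast genes these cells transcribe was not measured here. Longer gene spans did not account for the longer cover, since the list median lay above 100% of lists matched on window length in each library. Random lists were drawn from all protein-coding genes, and the housekeeping list also lay above at least 99.37% of them in each library. The controls are among these libraries, so the pattern holds without TNF, and the test of TNF only restated this. A minor share of stellate cells or fibroblasts in the culture could leave lower scores at their genes. The median best score percentile was instead higher than at pan-endothelial genes in all 4 libraries, by 5.12 at the least, but that interval over resampled genes ran from -3.14 to 27.95, and a longer cover gives more peaks to take the best from. Mixed cells, and endothelial cells that acetylate these genes in culture, therefore cannot be told apart.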
